A study of Mus musculus with 14 samples.

How the data were processed

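Total RNA from mouse GV oocytes was profiled on Illumina mouse BeadChips in 14 samples. Per the labels' protocols, mice received 5 units of pregnant mare serum gonadotropin 48 h before the oocytes were injected, and oocytes were collected in medium with 2 µM milrinone, which blocks the resumption of meiosis. Oocytes were cultured overnight, and RNA was isolated with a PicoPure kit, amplified with Nugen chemistry and labelled with biotin. The labels state that 1 set received miR-15a mimic, and do not state what was injected in the other set.

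The authors deposited a raw and a normalized table for each set. The raw tables hold a signal intensity and a detection p-value for each probe and array, per the file headers. The deposited normalized tables hold log2 signal. Their values equalled a quantile normalization of the log2 raw signal within each set, without background correction, to within 4.97e-14. The deposited series value table equalled the normalized tables to within 5.00e-09, so its scale is log2, it is not centred, and its column medians are 6.38 without mimic and 7.24 with mimic. Scanner, software and further steps are not given in the sources used here.

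For the comparisons, the raw intensity was background corrected with nec of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16, then log2 transformed and quantile normalized within each set. Offset and background keep fold changes of dim probes smaller than those of the transcripts. Gene names came from the platform annotation given with the series: 23978 of the 25697 probes had 1 symbol and 1719 had several or none, which stayed unnamed. Of the probes, 23962 were matched by gene identifier to the RefSeq gene table of GRCm38.p6, which changed 0 symbols. No coordinates are given, because the files name no genome build.

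A probe entered a comparison when its detection p was under 0.05 on at least as many arrays as the smaller group holds, and each gene was represented by its brightest probe. This left 9546 genes without mimic, 9883 with mimic and 9109 that passed in both sets on the same probe. Groups were compared with limma (lmFit and eBayes, two-sided) and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. The difference of the Cre effects was a contrast in a fit of all 4 groups, each effect being taken inside its own set. Mimic was not tested against no mimic, since it coincides with the table. Fold changes of probes not detected on any array of a group are bounds against the lowest detected signal of each array.

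Gene lists were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry, adjusted over the lists. The lists covered literature targets of miR-15 and miR-16, RNA silencing and mRNA decay, endo-siRNA regulated genes, oocyte and maternal-effect genes, meiotic spindle and checkpoint, p53 and DNA damage, stress, interferon response, granulosa and cumulus cells, theca and stroma, blood and immune cells, embryonic genome activation, ribosomal proteins and the mitochondrial respiratory chain. Of these 14 lists, theca and stroma (1 measured gene) and blood and immune cells (2 and 1) had fewer than 3 measured genes and were not tested. Acta2 stood at -0.04 without and 0.11 with mimic, Laptm5 at -0.17 and -0.08. Seed-site searches and heptamer ranks need transcript sequences, which were not used here, so the miR-15 question rests on the literature list alone.

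Groups, tests, lists and alternatives were fixed before the data were examined. Named genes were, for each comparison and direction, the 10 largest changes among genes past the threshold whose groups did not overlap. Where fewer than 5 passed, the 5 with the smallest p in that direction were taken. To these were added the leading members of each list, and Ago2 always. All probes of named genes were inspected. The alternatives were a replicate block, no background correction, median scaling, the deposited normalized and series values, no filter, detection on every array, every probe tested, eBayes with trend and robust settings, array weights, a spread shared by all groups, and leaving out each array.

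The procedure was tested on simulated data, with 200 changed genes among the real genes' means and spreads. Without mimic 94.0% of genes changed by 1 on the log2 scale and 56.7% of those changed by 0.5 were called, with mimic 74.6% and 32.8%, and in the difference 83.6% and 26.9%. All genes changed by 2 were called in each. The simulated noise was independent between genes, and 176, 143 and 145 genes were called in all. The real comparisons called 4, 13 and 0 genes, so their adjustment was stricter. The simulated shares are therefore too high for the real data, and few calls there do not show that changes of this size are absent. Among the calls were 9 unchanged genes of 9346 without mimic, 5 of 9683 with mimic and 5 of 8909 in the difference. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.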

Results

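Gene expression was measured on 14 one-colour Illumina BeadChips in fully grown mouse oocytes held at the germinal vesicle (GV) stage, that is, in prophase of meiosis I with the nuclear envelope intact. The oocytes carried a myc- and GFP-tagged human AGO2, the Argonaute protein that slices transcripts paired with a small RNA, at the Rosa26 locus behind a loxP-flanked stop cassette. In Zp3-Cre-positive oocytes the oocyte-specific Zp3 promoter drives Cre, which removes the stop. In Zp3-Cre-negative oocytes the stop remains. The first set held 4 Cre-negative and 4 Cre-positive samples without an added microRNA, and the second set held 3 Cre-negative and 3 Cre-positive samples with 2 µM miR-15a mimic, a synthetic duplex of that microRNA. Each set formed its own signal table, so presence of the mimic and table were the same split of the arrays. The labels do not say whether the samples came from separate animals or pools, and p-values therefore measure only the spread between these samples.

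The mean raw signal per array lay between 118 and 151 intensity units without mimic and between 339 and 380 with mimic. Of the 25697 probes, between 11652 and 13619 were detected on an array of the first set, and between 13129 and 13715 on an array of the second. Without mimic, Cre_pos replicate 1 had the 11652 probes and the other arrays 13294 or more. Cre_pos replicate 4 stood apart on the first principal component of its set, at 24.1 against -6.75 to 2.68 for the others, and correlated least with them (median r 0.977). The 95th percentile of raw signal was 3.80 to 5.28 times the median without mimic and 8.19 to 9.63 times with mimic. Oocyte and maternal-effect genes, such as those of the zona pellucida, gave a median log2 signal of 9.21 without mimic, with 39 of 40 genes detected. Markers of granulosa and cumulus cells, which surround the oocyte in the follicle, gave a median of 4.28 with 8 of 26 genes detected. Of the theca and stroma markers 1 of 11 was detected, and of the blood and immune cell markers 2 of 9. With mimic 9 granulosa markers, 1 theca marker and 1 blood marker were detected. The number of arrays limits the precision of every comparison.

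The Ago2 transcript was examined in every sample, because the labels give Cre status, and Cre removes the stop in front of the AGO2 transgene. Ago2 was higher in every Cre-positive sample than in any Cre-negative sample of its set. Without mimic its log2 signal was 4.89 ± 0.183 (SD, n = 4) in Cre-negative and 6.86 ± 0.0948 (SD, n = 4) in Cre-positive oocytes. This was a 3.93-fold difference, with 1 SE spanning 3.64- to 4.24-fold (limma adjusted p = 2.04e-08, exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 can give). With mimic the log2 signal was 6.08 ± 0.168 (SD, n = 3) and 8.43 ± 0.0983 (SD, n = 3), a 5.11-fold difference with 1 SE spanning 4.72- to 5.53-fold (limma adjusted p = 0.000338). The exact permutation p was 0.1, the smallest that 3 against 3 can give. Without background correction the log2 differences were 0.96 and 1.32. The array carries 1 Ago2 probe (ILMN_2609056), designed for the mouse gene, and whether it binds the human transcript was not tested.

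**Figure D1:**
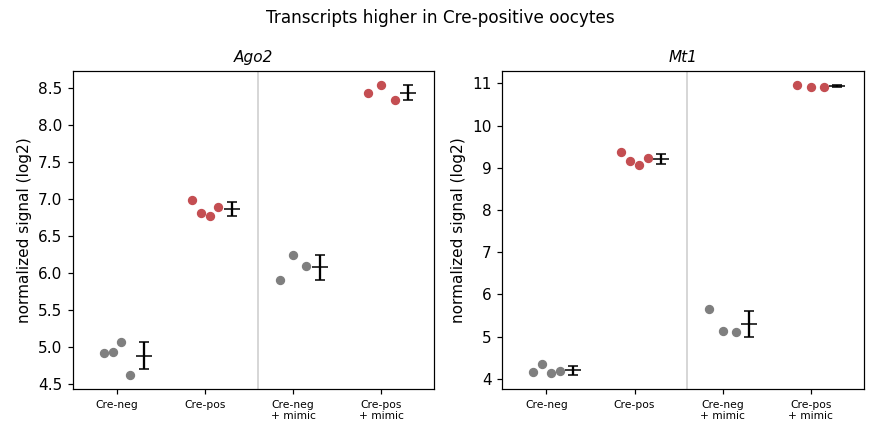
Normalized log2 signal of Ago2 and Mt1 on each of the 14 arrays (points, 1 per array), with the group mean and SD beside the points; the vertical line separates the sets, which were normalized separately. Every Cre-positive array lies above every Cre-negative array of its set for both genes.

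The comparison of Cre-positive with Cre-negative oocytes without mimic asks what Cre, together with the AGO2 transgene it switches on, does to the transcriptome. No group held Cre without the AGO2 transgene, so their effects cannot be told apart. Only 4 of 9546 genes passed. Besides Ago2, the metallothionein gene Mt1 (probe ILMN_2596522), which encodes a small metal-binding protein, was at least 29.0-fold higher in Cre-positive oocytes after background correction (n = 4 and 4, limma adjusted p = 5.29e-15). In Cre-negative oocytes Mt1 was detected on 1 of 4 arrays, at a mean log2 signal of 4.21, below the detection floors of 4.35 to 4.36. Its fitted log2 difference, 5.01 ± 0.105 SE, therefore depends on the offset added after background correction, and was 7.44 at an offset of 1 and 3.07 without background correction. Lower in Cre-positive oocytes were Vamp3, a vesicle SNARE of recycling endosomes, by 2.28-fold (log2 -1.19 ± 0.149 SE, adjusted p = 0.00154), and Plin3, a lipid droplet coat protein, by 2.01-fold (log2 -1.01 ± 0.162 SE, adjusted p = 0.0266). Both Vamp3 probes gave nearly the same fall, at -1.19 and -1.23.

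Below the threshold, the smallest p-values among higher genes belonged to B3gnt2 (log2 0.45), Tfec, a transcription factor of the Mitf family (0.47), and Acsf3, a mitochondrial acyl-CoA synthetase (0.39). Among lower genes they belonged to Tstd2 (-0.57), Cln6, a membrane protein of the endoplasmic reticulum (-0.50), and 6030458C11Rik (-0.49). Tfec was detected on 1 of 4 Cre-negative arrays and Cln6 on 1 of 4 Cre-positive arrays, so these 2 sizes rest on background. None of the 6 passed, with limma adjusted p between 0.342 and 0.600. An unadjusted p under 0.05 was reached by 446 genes, where 477 are due by chance. The call of Plin3 was lost without Cre_neg replicate 2, 3 or 4, without Cre_pos replicate 1, and without background correction. With no filter on dim probes both lower genes were lost and 2 genes remained.

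None of the 12 tested gene lists passed in this comparison. Among 26 measured genes reported in the literature as targets of miR-15 and miR-16, 0 passed either over all genes or adjusted over the list alone, and the median log2 difference was -0.05 (camera adjusted p = 0.903). Within it, Arl2, a small GTPase, stood at -0.35 and Bace1, the beta-secretase, at 0.33. The RNA silencing and mRNA decay machinery had 34 measured members, and Ago2 alone passed. Among 5 genes regulated by endogenous siRNAs in mouse oocytes, whose cleavage needs Argonaute 2, the median was -0.02 (adjusted p = 0.903), with Kif4 at -0.14 by its brightest probe (0.13 and 0.11 by its others) and Rangap1 at 0.07. Of 39 oocyte and maternal-effect genes none passed, with Nlrp5 at 0.71 by its brightest probe (0.61 and 0.07 by its others) and Obox1 at -0.20. Nor did any of 23 meiotic spindle and checkpoint genes, where the microtubule-binding Numa1 stood at -0.33 and the kinetochore motor Cenpe at 0.29. Adjusted over the list alone, Ago2 passed, and so did Tcstv1 of the embryonic genome activation list, which was 1.24-fold lower (log2 -0.32 ± 0.104 SE, adjusted p = 0.948 over all genes). The other embryonic genome activation genes did not pass. Medians of the remaining lists were 0.00 for p53 and DNA damage response genes, -0.03 for stress genes, -0.10 for interferon response genes, 0.09 for granulosa markers, 0.01 for ribosomal protein genes and 0.02 for mitochondrial respiratory chain genes.

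The comparison of Cre-positive with Cre-negative oocytes in the presence of miR-15a mimic asks whether added AGO2 lets an abundant microRNA lower its targets. Here too, Cre and the AGO2 transgene came together. In this set 13 of 9883 genes passed, 2 higher and 11 lower, and an unadjusted p under 0.05 was reached by 741 genes, where 494 are due by chance. Mt1 was 49.5-fold higher (log2 5.63 ± 0.155 SE, n = 3 and 3, limma adjusted p = 1.03e-05; log2 6.33 at an offset of 1 and 3.73 without background correction) and, as given above, Ago2 was the other higher gene. Vamp3 fell 6.66-fold (log2 -2.74 ± 0.246 SE, adjusted p = 0.0103), and its other probe gave -2.73. Plin3 fell 3.48-fold (log2 -1.80 ± 0.145 SE, adjusted p = 0.00578).

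The other genes that fell included the small GTPases Rab23 (2.41-fold, log2 -1.27) and Rab11b (2.18-fold, log2 -1.12), the latter a regulator of recycling endosomes. The zinc finger gene Zfp345 was 2.51-fold lower, 6030458C11Rik 2.12-fold, Tstd2 2.05-fold and Kif24, a kinesin, 2.04-fold. Dtna, encoding alpha-dystrobrevin, was 1.89-fold lower by its 1 detected probe, with 3 further probes below detection on all arrays of the set. The brightest probe of Gucy1a1, a subunit of soluble guanylate cyclase, was detected on all 3 Cre-negative arrays and on none of the Cre-positive arrays. By this probe Gucy1a1 was at least 1.55-fold lower. That bound sets the Cre-negative mean against the detection floor of the Cre-positive arrays. A second Gucy1a1 probe passing the filter was detected on 4 arrays of the set and gave a log2 difference of only -0.11. A further probe, detected on 2 arrays and not passing the filter, gave -0.55. The bound therefore holds for the first probe alone. The 11th lower gene, Mab21l3, fell 1.84-fold and is named here after its value was seen, because it lay outside the 10 largest falls. Adjusted p-values of these 9 genes lay between 0.00578 and 0.0485. Among higher genes that did not pass, Tfec stood at log2 0.82 (adjusted p = 0.0688), Miip at 0.53, and Fcrl1, detected on 0 of 3 Cre-negative arrays, was at least 1.13-fold higher.

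The number of calls changed when single arrays were left out. The 13 genes became 2 without Cre_neg replicate 1 or 2, 7 without Cre_neg replicate 3, 6 without Cre_pos replicate 1 and 5 without Cre_pos replicate 2, all with mimic. Vamp3 and Plin3 were each lost without Cre_neg replicate 1 or 2 or Cre_pos replicate 2, whereas Mt1 and Ago2 passed in every one of these fits. With single arrays left out the log2 difference of Vamp3 lay between -2.98 and -2.53 and that of Plin3 between -1.94 and -1.66. Zfp345, Rab23, Tstd2 and Dtna were each lost in 5 of the 6 fits with 1 array left out, and Gucy1a1 in all 6. Without background correction Vamp3 and Plin3 were -1.57 and -1.13 and still passed, while Gucy1a1 was -0.27 and was lost. The Gucy1a1 call was lost in 11 of 16 alternatives. In all, 21 genes passed without background correction, and 26 with eBayes trend and robust settings.

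**Figure D2:**
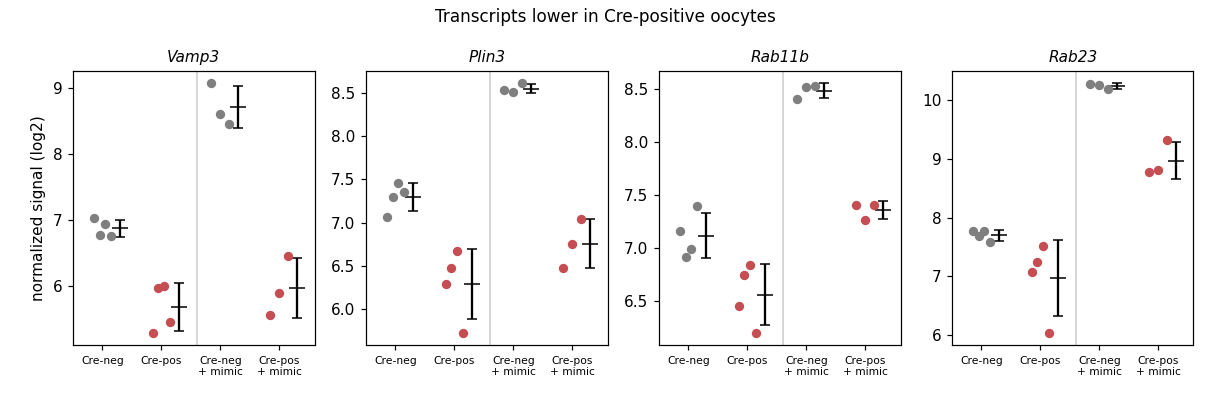
Normalized log2 signal of Vamp3, Plin3, Rab11b and Rab23 on each array (points), with the group mean and SD; the vertical line separates the sets, which were normalized separately. Cre-positive arrays lie below all Cre-negative arrays of their set, and the falls with mimic are -2.74, -1.80, -1.12 and -1.27 on the log2 scale.

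With mimic present, the 29 measured literature targets of miR-15 and miR-16 held no gene that passed, over all genes or adjusted over the list alone. Their median log2 difference was 0.00 and their mean -0.02 (camera adjusted p = 0.658). Fgfr1, a receptor tyrosine kinase, stood at -0.25 ± 0.0950 SE and Wee1, the kinase that restrains Cdk1, at 0.44 ± 0.195 SE. Again only Ago2 passed among 34 genes of the RNA silencing and decay machinery, and none of the 5 endo-siRNA regulated genes passed, with Ppp4r1 at 0.22 and Hdac1 at -0.12.

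Ribosomal protein genes and mitochondrial respiratory chain genes were higher in Cre-positive oocytes as lists. Of 57 ribosomal protein genes 47 lay above 0, with a median of 0.08, and of 71 respiratory chain genes 60 lay above 0, with a median of 0.05 (camera adjusted p = 0.00304 for each at the preset correlation). Both calls were lost at adjusted p = 0.690 with an estimated correlation. No member passed on its own, with Rpl29 at 0.43 (0.03 by its other probe), Rpl5 at 0.56, Ndufb10 at 0.39 and Uqcrb at 0.28. The ribosomal call was also lost without Cre_neg replicate 1 (adjusted p = 0.540) or Cre_pos replicate 1 (0.173), and the respiratory chain call without Cre_neg replicate 1 (0.266) or Cre_pos replicate 2 (0.0783). No other list passed. Among its members, Npm2, a maternal histone chaperone, stood at 0.71 and the oocyte growth factor Gdf9 at 0.43, Cenpe at 0.48, the p53 target Cdkn1a at 0.54 and the stress gene Chac1 at -0.34. Adjusted over the list alone, Isg15 of the interferon list was higher, by at least 1.15-fold, since it was detected on 0 of 3 Cre-negative arrays. It did not pass over all genes (adjusted p = 0.357).

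**Figure D3:**
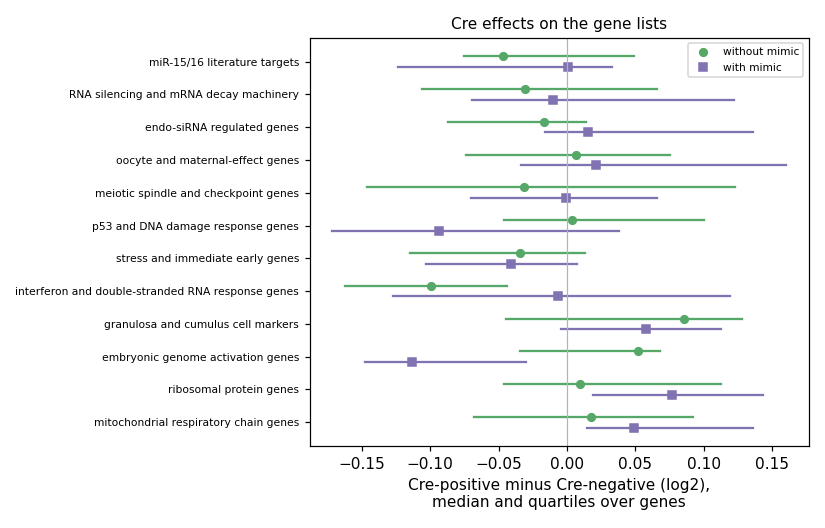
Median (symbol) and quartiles (bar) over the genes of each list of the log2 difference between Cre-positive and Cre-negative oocytes, without mimic (circles) and with mimic (squares). The medians of the miR-15/16 list are -0.05 and 0.00, and those of ribosomal protein genes 0.01 and 0.08.

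Whether the mimic changed the response to Cre was tested as the difference of the 2 Cre effects. No gene of 9109 passed (limma smallest adjusted p = 0.0606), and 414 had an unadjusted p under 0.05, where 455 are due by chance. The smallest p belonged to Trp53rkb, which differed by -1.28 ± 0.199 SE, from 0.17 without mimic to -1.10 with mimic. Vamp3 differed by -1.51 ± 0.278 SE and Zfp345 by -0.93 ± 0.172 SE (adjusted p = 0.115 for each), followed by the carboxypeptidase Cpb1 (-0.94) and the kinesin Kif15. The Kif15 probe used here was detected on none of the Cre-positive arrays with mimic, so the size of its difference rests on background. By the brightest Kif15 probe of the set with mimic, the gene was detected on 2 of 3 Cre-positive arrays, with a Cre effect of -0.72. The most positive by p were Cln6, the cytokine receptor Il20ra, the semaphorin receptor Plxna1 (0.72), the zinc finger factor Snai1 (0.80) and Ido2 (0.74). Cln6 and Il20ra were each detected on 0 of 3 Cre-negative arrays with mimic, and no size is given for them. Plxna1 and Snai1 were each detected on 2 of these 3 arrays, so their sizes rest in part on background. For Snai1 a second probe went the other way, with Cre effects of 0.33 without and 0.06 with mimic, against -0.33 and 0.47 for the probe used. Neither Ago2 (0.38 ± 0.162 SE) nor Mt1 passed. The direction of both rests on the offset, since at an offset of 1 the Cre effect on Ago2 was 2.82 without and 2.66 with mimic, and that on Mt1 7.44 and 6.33. None of the 12 lists passed, and the 26 miR-15/16 literature targets had a median difference of -0.01 (camera adjusted p = 0.891). Without background correction 3 genes passed, and with array weights 3.

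The same genes recurred across sets that share no array. Mt1 and Ago2 were called higher in both, where 0.000438 shared calls are due by chance, and Vamp3 and Plin3 were called lower in both, where 0.00219 are due. Of the 10 lower genes called with mimic and also tested without it, 9 were lower there too, 8 with an unadjusted p under 0.05. Their median log2 difference was -0.52 without mimic and -1.10 with mimic. The genes were chosen by their calls with mimic, which favours large falls there, so these medians do not compare the sizes fairly. Across 9109 genes the 2 Cre effects correlated at Pearson r = 0.338 and Spearman rho = 0.184. Genes are not independent replicates, so the arrays were regrouped. Of 350 splits 1 gave an r as large, the real one (permutation p = 0.00286), and 5 gave a rho as large (permutation p = 0.0143). Without Mt1 and Ago2 r was 0.237, and 1 other split gave a larger one, 0.240 (permutation p = 0.00571).

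**Figure D4:**
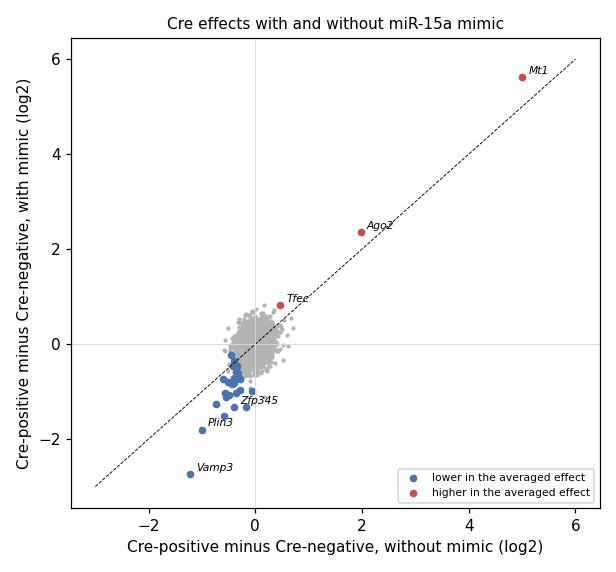
Log2 difference between Cre-positive and Cre-negative oocytes of 9109 genes without mimic (horizontal) and with mimic (vertical); coloured points are the 3 higher and 28 lower genes of the averaged effect described among the additional observations, and the dashed line marks equal effects. Mt1 lies at 5.01 and 5.63 and Vamp3 at -1.23 and -2.74.

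The mimic itself could not be tested, since all arrays with mimic were in the second table, and values from arrays normalized together are given as a description. In Cre-negative oocytes the median of the 26 miR-15/16 literature targets was 0.11 lower with mimic (log2 -0.11, at the 12.5th percentile of 10000 random lists matched on signal). In Cre-positive oocytes it was -0.05 (26.1th percentile). Among these targets, the cyclin gene Ccnd2 stood lower with mimic in both, at -1.63 and -1.59. Its log2 signal with mimic was 4.89 and 4.82, near the lowest of the list. The adhesion gene Cadm1 stood at -0.89 and -1.09. Higher with mimic were the laminin gene Lamc1, at 1.21 and 1.08, and Pafah1b2, at 0.79 and 0.87. These genes were chosen after their values were seen. Other lists lay farther out, with ribosomal protein genes at -0.21 and -0.13 and p53 response genes at 0.34 and 0.24. The values for the miR-15/16 list turned to 0.12 and 0.12 above the median of all genes in the deposited normalized tables.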

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

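The tests of the Mt1 rise, of single arrays and of signal range were chosen after their results had been seen in part. In the groups of 4 samples, 172 groups of values were checked for a sample standing apart from the other 3, by its gap to the nearest sample as a share of the range (above the 95% critical value of Dixon's Q), and 10 were found, where chance gives 8.6. This check is of single genes and lists, and does not speak to Cre_pos replicate 4, which stood apart over all genes (array weight 0.395). In Cre-negative oocytes these were Ccnb2 (0.923, replicate 1), Cdkn1a (0.890, replicate 4), Fgfr1 (0.869, replicate 3), Fosb (0.962, replicate 3), Kif15 (0.851, replicate 4) and Wt1 (0.931, replicate 4), all with the odd sample highest. In Cre-positive oocytes replicate 4 was lowest for Uchl1 (0.919) and Uqcrb (0.918), and replicate 1 was highest for Xpo5 (0.837) and lowest for the p53 list (0.865).

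Chance as the source of the calls was examined by regrouping the arrays. Without mimic, 1 of the 35 splits gave 4 or more genes, the real one, and the highest other gave 0. Regrouping thus did not reproduce this count, which includes Mt1 and Ago2, but it does not test each call singly. With mimic the real split gave 13 genes and the highest other 0 (1 of 10), and these 10 splits are too few for a share under 0.05. For the gene lists with mimic, 3 of 10 splits gave 2 or more past the threshold, the real one among them, so chance stays an open source of those calls. For the difference, regrouping decides nothing: all 100 of 100 drawn splits must give at least the real 0 genes.

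Mt1 rose more than any other gene, Ago2 included. A response of metal-regulated genes might raise it, in which case Mt2 and the zinc exporter Slc30a1 would rise too. Mt2 stood at a log2 difference of 0.32 ± 0.209 SE with mimic and was detected on 0 of 8 arrays without mimic, while Slc30a1 stood at 0.09 ± 0.0994 SE and -0.03 ± 0.109 SE. The flat Slc30a1 argues against a broad zinc response, but the dim Mt2 leaves this explanation open. Some Cre constructs carry Mt1 polyadenylation sequence, and a probe there could report the transgene, which cannot be told apart from the gene itself with 1 Mt1 probe and no sequences.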

How the results depend on the processing

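Leaving out Cre_pos arrays 1 and 4 together, the averaged Cre effect, its list tests, the offset of 1 and the correlation without Mt1 and Ago2 were chosen after seeing the data. The Cre effect without mimic gave 2 to 5 genes over all alternatives, with 3 to 5 when single arrays were left out and 2 with no filter on dim probes. The direction split was 2 higher and 1 lower without background correction. With mimic the count of 13 became 21 without background correction, in the deposited normalized table and in the series value table, 21 with median scaling, 26 with trend and robust settings and 25 with a spread shared by all 4 groups. It lay between 2 and 13 when single arrays were left out. The difference gave 0 genes with the main processing, 3 without background correction and in both deposited tables, and 2 with median scaling. It gave 1 with no filter, 3 with array weights and 0 to 4 when single arrays were left out. Ago2 and Mt1 passed in both sets under every alternative that tested them.

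Replicate numbers did not clearly pair the samples. Correlations of same-numbered deviations were -0.07 to 0.01 without mimic and 0.04 to 0.21 with mimic. In neither set did every sample correlate best with its own number. With mimic, samples of unlike number gave -0.198 to 0.139, and so few samples cannot exclude a pairing there. With the replicate number as a block the counts were 4, 3 and 0 genes for the 3 comparisons, with Plin3 the only lower gene left with mimic, and the number of lists that passed stayed at 0, 2 and 0.

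The number of lists that passed lay between 0 and 3 with mimic and between 0 and 1 in the difference when single arrays were left out. The adjusted p of the miR-15/16 list never passed, and its direction turned in some such fits, with adjusted p from 0.792 to 0.965 without mimic and from 0.579 to 0.999 in the difference. The ribosomal list without mimic turned likewise (0.291 to 0.965). Of the 2 lists that passed in the averaged effect, 0 passed with an estimated correlation and 0 with fry. Directions of unchanged single genes turned at values near 0: Rangap1 at -0.00915 with median scaling, Kif4 at 0.00585 and Mdm2 at -0.0456 without Cre_pos arrays 1 and 4. When single arrays were left out, Acta2 lay between -0.0989 and 0.0143 without mimic and between -0.00387 and 0.174 with mimic, Alas2 between -0.195 and 0.00321 without mimic, and Laptm5 between -0.000380 and 0.185 in the difference. The mimic minus no-mimic median of the miR-15/16 list, relative to all genes, moved from -0.11 to 0.12 in Cre-negative and from -0.06 to 0.12 in Cre-positive oocytes in the deposited normalized tables. The cause of these changes was not tested. A slide block was not run, since no slide is known, and the seed-site and heptamer results were not run for lack of sequences. The lower signal over background of the first set limits what can be measured for dim genes there.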

Other observations

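The average of the 2 Cre effects, its regroupings and the comparison of effect sizes were added after the data were seen. Averaged over both sets, 31 of 9109 genes passed (limma), 3 higher and 28 lower, and each had the same direction in both sets. Besides Mt1 and Ago2 the higher gene was Tfec (log2 0.64 ± 0.0790 SE, adjusted p = 0.000300), which without mimic was detected on 1 of 4 Cre-negative arrays. Lower genes outside those already described included Ccdc127 (-1.05), the semaphorin Sema4b (-0.67), the tetraspanin Tspan31 (-0.66), Mrap, an accessory protein of the ACTH receptor (-0.63), the RNA exosome subunit Exosc4 (-0.63), the complement gene C1qb (-0.60) and the actin-severing cofilin gene Cfl1 (-0.53). These 7 were picked from the table of called genes. The Cfl1 probe was detected on only 1 of 3 Cre-positive arrays with mimic, so the size of its fall rests in part on background. Left-out arrays gave 21 to 41 genes. Of 100 drawn splits 1 gave as many as 31 genes, the real one, and the highest other gave 19. Regrouping thus did not reach this count, which includes Mt1 and Ago2. Since another split gave 19, some of the 31 calls may still be due to chance. Among lists, ribosomal protein genes (median 0.05, adjusted p = 0.0378) and respiratory chain genes (0.04, adjusted p = 0.0318) were higher at the preset correlation, and neither passed with an estimated correlation (adjusted p = 0.724 and 0.639).

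The fall of the 28 genes may have a technical source. A chromosome segment linked to the Cre transgene would place them near each other. Of the 26 genes with a known position, 2 had another within 100 neighbouring genes in the RefSeq gene order of GRCm38.p6. This share of 0.0769 stood against a median of 0.0769 in random draws (95% range 0 to 0.308). It argues against a segment holding most of these genes, while a segment holding only a few would not be detected. Without any 1 array the median averaged change kept at least 0.965 of its size. The genes were called on all arrays, however, which already favours a small spread within groups. This result therefore says little about a single outlying array. Cleavage or repression by AGO2 loaded with small RNAs is a biological hypothesis that stays open, since no transcript or small RNA sequences were used. An effect of Cre itself cannot be told apart from it in these groups.

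Falls were larger with mimic. For 25 genes lower in a precision-weighted average, chosen so that it is uncorrelated with the difference, the median was -0.40 without and -0.81 with mimic, a ratio of 2.03 (95% bootstrap interval over genes 1.60 to 2.61), and 23 of the 25 fell more with mimic (fry p of the difference = 0.000294). The 25 genes were chosen by their p on these same arrays, which favours a small spread within groups. The fry p uses that spread again and may be too small. A wider signal range of the mimic arrays could stretch effects. Levels of genes in the same signal range spread 1.24 times wider with mimic, below that interval. The interval resamples genes measured on the same arrays and leaves out the spread between arrays, so this does not decide the question. An offset of 1 in place of 16 lowered the ratio to 1.67 (1.33 to 2.29, again over genes) and the ratio of the Ago2 rises from 1.19 to 0.941. The ratio thus depends in part on the offset. Mimic and table coincide, and whether the mimic or another difference between the sets underlies the larger falls cannot be decided here.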
